A study of Mus musculus with 76 samples.

How the data were processed

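Macrophages of the mouse atrioventricular (AV) node, the tissue that relays the heartbeat from the atria to the ventricles, were profiled by single-cell RNA sequencing. Per the labels' protocols, the triangle of Koch was dissected from perfused hearts of wild-type C57BL/6J mice, digested with collagenases, DNase and hyaluronidase, and sorted for living cells low in lineage markers of lymphocytes, neutrophils and erythroid cells, high in CD45, CD11b and F4/80, and low to intermediate in Ly6C. Single cells were captured on a Fluidigm C1 microfluidic chip, chambers seen to be empty were excluded, cDNA was made with the SMARTer Ultra Low RNA kit and libraries with Nextera XT, per the labels' protocols. This chemistry reads whole transcripts, holds no molecular identifiers and keeps no strand. Reads from a gene and its antisense partner could therefore not be told apart, and amplified copies of 1 molecule were counted separately.

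The authors deposited counts per 1000000 (CPM), rounded to 1 decimal, for 9235 genes in 76 libraries, each of which is 1 cell. Every deposited column summed to 1000000 CPM within rounding. The submitters' processing notes name STAR 2.3.0, HTSeq 0.6.0 and the build mm9; the annotation is not given in the sources used here. Every gene with values was above 0 in at least 6 libraries, so the CPM are relative to the genes that have values. Symbols were matched without regard to case to the reference annotation, which carries another build, so no coordinates were used: 8378 symbols were current, 743 were older names and 114 had no match. Older names are printed as the table gives them. Genes without values in the table, among them all connexins and pannexins, Xist and the genes of the NK cell, mast cell or basophil, smooth muscle cell or pericyte, and erythroid lists, are not analysed here.

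Because CPM is a whole number of reads divided by a constant, the CPM of 1 read was estimated in each library as the largest step of which the low values, up to 60 steps, were whole multiples. In the library with the poorest match 96.2% of these values, and in the median library 100% of them, were whole multiples within 0.051 CPM. The estimated depth ranged from 259554 to 6289414 reads per library, with a median of 2124946. On 11 simulated libraries 10 depths were recovered within 1%, but 1 of 6000000 reads was estimated as 4001000, so the depths are estimates and the deepest libraries may be deeper than stated. Depth and detection differed between cells: 2324 to 4382 genes were above 0 per library. Of the values above 0, 45.5% lay below 10 CPM, which is why the counts over lists are given at both thresholds. Counts for single genes are those above 0 unless 10 CPM is named. Intervals cover the sampling of cells only. The recovered reads were used to compare libraries with each other and to thin cells to equal depth. No count model was fitted to them, since a single group offers no comparison between groups.

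The libraries of transcriptomes 13 and 19 were nearly identical. Their log2(CPM + 1) values had a Pearson correlation of 0.978, against at most 0.421 in the other 2849 pairs, and a chi-square test of their recovered reads gave 1.30 per degree of freedom over 1751 genes, against at least 131 in every other pair. That is slightly above the value of 1 that sampling alone gives, and far closer to it than for any other pair. The pair was counted as 1 cell, by the mean of both libraries, so that n = 75. This was decided after the data were examined, against a written design of 76 cells, and both counts are compared in the closing section.

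The labels name no animal, chip or batch, so the cells are 1 sample. No test between groups was possible, and the p-values below were made by permuting cells. They describe these cells and say nothing about the spread between animals. Doublets were not called, and no cell was left out. Gene lists, the tests of the report and the rule for named genes were fixed before the data were examined, and tests added later are named as such in the closing section. The lists held 14 programmes without shared genes, 7 groups of ion channels, exchangers, pumps and receptors, growth factors and matrix regulators, markers of 15 cell types, the sort markers and sex-linked transcripts. The named genes are, per list, the 4 members detected in the most cells, every sort marker, the 10 most abundant and the 20 most variable genes, the 10 largest positive and 10 largest negative correlations with the MHC class II score, the top 10 genes by fold of each cluster, and the Y-linked genes; a selection of these is printed. Correlations with Gja1 had been planned and were not run, because Gja1 is not analysed here.

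Detection was the share of cells above 0 CPM with an exact 95% Clopper-Pearson interval. A programme's score in a cell was the mean over its members of standardised log2(CPM + 1), over genes detected in at least 8 cells. Coherence was the mean pairwise Spearman correlation of a list's members, set one-sided against 10000 random lists matched on mean expression in 20 bins. Scores were compared by Spearman and Pearson correlation with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05, adjusted by the method of Benjamini and Hochberg over 91 pairs or over all genes tested. Each correlation was repeated without the 2 cells farthest from the median of 1 score, and in the 37 cells with fewer and the 38 cells with more genes detected. For pairs of scores this was the MHC class II score where it took part, and otherwise the tissue-resident score. For the immediate early and inflammatory pair it was the inflammatory score. Variable genes were ranked by the excess of log squared coefficient of variation over its lowess trend (fraction 0.3), with a mean of at least 10 CPM. Cells were clustered by Ward linkage on 10 principal components of the 500 most variable genes, with 2 to 6 clusters chosen by the mean silhouette.

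The correlation test was checked on simulated data made by shuffling each of the 8341 genes tested over cells and giving 200 of them a known relation with the MHC class II score. It called 13 of 50 genes given a correlation of 0.4, 29 of 50 at 0.5, 42 of 50 at 0.6 and 49 of 50 at 0.7, and 8 of 8141 shuffled genes. In the same cells, with 8351 genes, the coherence test called the 1 list given a shared order and 0 of 13 shuffled lists, and 0 of 91 pairs of scores were called. Shuffling each gene on its own removed the relations between genes and the differences in detection between cells. The counts of shuffled genes, lists and pairs called may therefore not hold for the real cells. A given correlation was set before values with many ties at 0 were placed, so the correlation reached may be smaller. Of 200 among 6780 simulated genes given 4 times the squared coefficient of variation, 88 ranked among the first 200, so the ranking of variable genes is coarse. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and leidenalg 0.10.2. Alternatives covered the detection threshold, the pseudocount, the gene filter, adjustment for genes detected, scaling, the cells kept, reads thinned to 250000 per cell, and the clustering.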

Results

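Transcriptomes of single macrophages sorted from the atrioventricular (AV) node of wild-type mice were measured to describe the cells of 1 group, with no treated or control arm. The 76 libraries held an estimated 259554 to 6289414 reads, with a median of 2124946, and 2324 to 4382 genes above 0. The pair of nearly identical libraries, transcriptomes 13 and 19, was counted as 1 sample, which left 75 cells. Values are CPM as mean ± SD over these cells (n = 75) unless stated otherwise, and shares carry exact 95% Clopper-Pearson intervals that cover the sampling of cells only.

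The cells carried the transcripts of macrophages at high level. The most abundant was Lyz2, which encodes lysozyme, at 22689 ± 10199 CPM. It was followed by Cd74, the invariant chain of MHC class II, at 17587 ± 17423 CPM, Actb at 16987 ± 7761 CPM, Malat1 at 14835 ± 9662 CPM, and the apolipoprotein Apoe at 11402 ± 10263 CPM. Ctsb, H2-Ab1, H2-Aa, C1qb and Sepp1 completed the first 10, which together took 12.7% ± 3.21 of all CPM. All 16 macrophage markers were above 0 in at least 50% of the cells, and 12 of them reached 10 CPM in at least 50% of the cells. Csf1r, the receptor for colony stimulating factor 1, was above 0 in 75 of 75 cells (lower bound 95.2%) and averaged 2659 ± 2243 CPM; Tyrobp and Maf were above 0 in every cell as well. The transcripts of the proteins used for sorting were detected in most cells. Emr1, which encodes F4/80, and Ptprc, which encodes CD45, were each above 0 in 74 cells, and Itgam, which encodes CD11b, in 66 cells.

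Of the 20 markers of other cell types with values, 3 were above 0 in at least 50% of the cells and 2 reached 10 CPM in that share. Pf4, listed for platelets, was above 0 in 74 cells and averaged 1882 ± 1554 CPM. Ighm, the heavy chain of immunoglobulin M listed for B cells, was above 0 in 69 cells and reached 10 CPM in 51 cells, or 68.0% (56.2 to 78.3%), with a mean of 868 ± 1299 CPM. The B cell gene Cd79b was above 0 in 6 cells and reached 10 CPM in 5. Ebf1 was above 0 in 21 cells and reached 10 CPM in 0 of 75, which allows a share of up to 4.80%. Gsn, listed for fibroblasts, was above 0 in 40 cells and at 10 CPM in 17. Among cardiomyocyte genes Ttn, which encodes titin, was above 0 in 26 cells at 2.33 ± 6.88 CPM. Myh6, which encodes a myosin heavy chain, was above 0 in 22 cells at 15.0 ± 67.4 CPM, and each of these reached 10 CPM in 6 cells. Tnnt2 was above 0 in 10 cells and Tnni3 in 8, and they reached 10 CPM in 1 and 3 cells. Among dendritic cell markers Siglech was above 0 in 31 cells, Batf3 in 30, Kmo in 25 and Cd209a in 18. They reached 10 CPM in 13, 18, 12 and 7 cells. Nr4a1, the only monocyte gene with values, was above 0 in 34 cells. Eng, listed for endothelium, and Csf3r, listed for neutrophils, were each above 0 in 16 cells, and Lck, listed for T cells, in 7. For neurons or Schwann cells, Mbp was above 0 in 23 cells and S100b in 7. Y-linked transcripts were above 0 in 66 cells, with Ddx3y in 44, Eif2s3y in 41, Kdm5d in 26 and Uty in 23.

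Genes that move or sense ions were examined because the AV node conducts electrically. Connexins and pannexins were not analysed here. Of 205 listed channels, exchangers, pumps, connexins and receptors, 67 had values and 17 were above 0 in at least 50% of the cells. The count was 6 at a threshold of 10 CPM and 8 after thinning every cell to 250000 reads, an alternative added after the data were examined. The calcium pump of the plasma membrane Atp2b1 was above 0 in every cell and averaged 532 ± 639 CPM. Slc9a9, a sodium and proton exchanger of endosomes, was above 0 in 67 cells at 528 ± 993 CPM, Atp1b3 in 56 and Atp2a2 in 41. All 6 genes with values on the list of nucleotide and transmitter receptors were above 0 in at least 50% of the cells, and 2 of them reached 10 CPM in that share. The nucleotide receptors P2ry6, in 64 cells at 314 ± 575 CPM, and P2rx4, in 60 cells at 381 ± 758 CPM, led this list, P2ry12 was above 0 in 52 cells and P2rx7 in 50. Among chloride channels Clic1 was above 0 in 67 cells, the volume-regulated channel subunit Lrrc8a in 60, Ano6 in 51 and Clic4 in 43. Of 17 calcium and TRP channels with values only Trpm7 was above 0 in at least 50% of the cells, in 43 of 75, followed by Trpv4 in 26, the mitochondrial uniporter Ccdc109a in 25 and Itpr2 in 24. None of the 9 potassium channel genes or the 3 sodium and pacemaker channel genes with values reached that share. At 10 CPM it was reached by 2 chloride channel genes, 2 exchanger or pump genes and 0 calcium and TRP channel genes. Kcnab2 was above 0 in 22 cells, Kcnk6 in 18, Kcnk13 in 14 and Tmem175 in 12. Tpcn1 was above 0 in 17 cells, and Scn2b and Scn3b in 6 each.

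**Figure D1:**
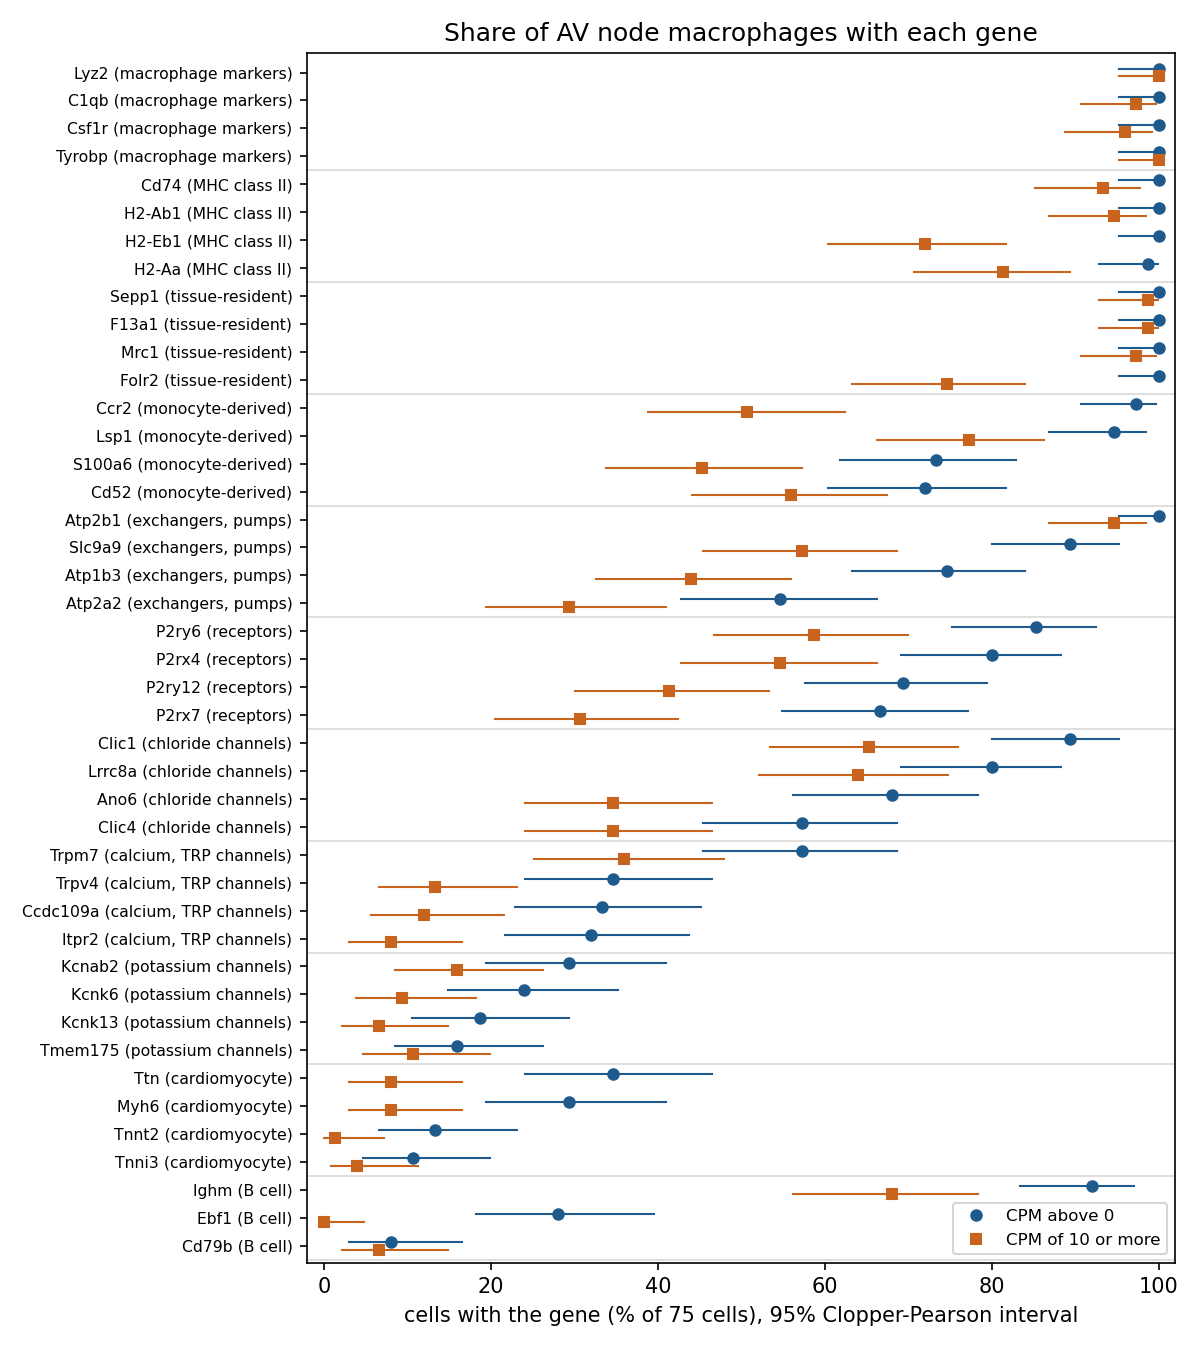
Share of the 75 cells, in percent, with each of up to 4 leading genes of 11 lists, above 0 CPM (circles) and at 10 CPM or more (squares), with exact 95% Clopper-Pearson intervals as lines. Macrophage genes lie near 100% at both thresholds, whereas Ccr2 falls from 97.3% to 50.7%.

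The lists of macrophage programmes differed in how widely and how strongly they were expressed. Of 313 programme genes with values, 226 were above 0 in at least 50% of the cells, and 151 at a threshold of 10 CPM. All 19 lysosome genes were above 0 in that share of cells, led by the cathepsins Ctsb, at 9859 ± 7625 CPM, Ctsc and Ctss, and by Laptm5. So were 15 of 16 tissue-resident genes, led by Sepp1 at 6997 ± 4854 CPM, the coagulation factor gene F13a1 at 6120 ± 5041 CPM, the mannose receptor Mrc1 at 3192 ± 2553 CPM and Folr2 at 1785 ± 1792 CPM. Of 21 immediate early and heat shock genes 20 were above 0 in at least 50% of the cells, led by Btg2, Fos, Hspa8 and Egr1. Fos averaged 2510 ± 3264 CPM. The same share was reached by 7 of 10 MHC class II genes and 9 of 13 complement and clearance genes, among the latter C1qb, C3ar1 and Cfp. It was reached by 8 of 11 lipid genes, led by Apoe, Cd36, Abca1 and Plin2, and by 7 of 12 iron and haem genes, led by Fth1, Ftl1, Blvrb and Hmox1. Of 13 glycolysis genes 7 reached it, led by Aldoa, Ldha, Pkm2 and Eno1. Of 15 inflammatory genes 7 did, led by Nfkbia, Nfkbiz, Ccl2 and Cxcl16, and of 7 monocyte-derived genes Ccr2, Lsp1, S100a6 and Cd52. Among 14 interferon response genes 5 reached it, led by Rtp4 in 60 cells, Ifi204 in 54, and Oas1a and Oasl2 in 39 each. Pcna, in 42 cells, was the only one of 9 cell cycle genes to do so, ahead of Mcm4 in 27, Mcm5 in 20 and Mcm3 in 19. Of 80 ribosomal protein genes 59 reached it, among them Rps3, Rpl4 and Rps9. Of 73 respiratory chain genes 58 did, led by Cox8a, Cox6a1, Atp5b and Atp5d. At 10 CPM every one of these counts was lower. They were 18 for lysosome, 12 for tissue-resident, 13 for immediate early, 6 for MHC class II and 7 for complement genes. Lipid and iron genes had 3 each, glycolysis genes 6, inflammatory genes 2, monocyte-derived genes 3, interferon genes 1 and cell cycle genes 0. Ribosomal protein genes had 49 and respiratory chain genes 28. Among 16 growth factor and matrix genes with values, Timp2 was above 0 in 71 cells and Igf1 in 68, at 847 ± 1412 and 904 ± 1066 CPM, whereas Mmp9 was above 0 in 22 and Bmp2 in 21.

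Members of 12 of the 14 programmes varied together from cell to cell by more than matched random lists did. The mean pairwise Spearman correlation over cells was 0.375 for MHC class II, 0.333 for tissue-resident, 0.325 for monocyte-derived, 0.198 for immediate early and heat shock and 0.168 for interferon response genes, where the medians of random lists lay between 0.00826 and 0.0159. Each of these had an adjusted p of 0.000175, and its raw p of 0.0001 is the smallest that 10000 random lists can give. Of the others, ribosomal protein genes reached 0.102, iron and haem genes 0.0853, lysosome genes 0.0795, inflammatory genes 0.0723, complement genes 0.0717, respiratory chain genes 0.0716 and cell cycle genes 0.0622. The cell cycle list, with an adjusted p of 0.0210, did not pass over genes detected in at least 20 cells or without the cells in the lower quartile of genes detected. Lipid genes, at -0.00753 (adjusted p = 0.89), and glycolysis genes, at 0.0287 (adjusted p = 0.194), did not pass. The glycolysis list passed when values below 10 CPM were set to 0.

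MHC class II and tissue-resident transcripts ran in opposite directions. The MHC class II genes took 4.39% ± 4.36 of all CPM, with a range from 0.000800% to 17.4%. H2-Aa, which encodes the α chain of I-A, reached 10 CPM in 61 cells and 1000 CPM in 50. Cells with a higher MHC class II score had a lower tissue-resident score, with a Spearman rho of -0.554 (p = 1e-05, the smallest the permutations can give; adjusted p = 0.000303) and a Pearson r of -0.572 (p = 1e-05). Without the 2 cells farthest from the median MHC class II score r was -0.546, and rho was -0.532 in the 37 cells with fewer genes detected and -0.621 in the 38 with more. The monocyte-derived score, led by the chemokine receptor Ccr2, fell as the tissue-resident score rose, with rho = -0.605 (p = 1e-05; adjusted p = 0.000303) and r = -0.664 (p = 1e-05), and r = -0.612 without 2 cells. It rose with the MHC class II score, with rho = 0.419 (p = 0.00019; adjusted p = 0.00157) and r = 0.489 (p = 1e-05), and r = 0.430 without 2 cells, but rho was 0.124 in the cells with fewer genes detected and 0.637 in those with more. At 100 CPM, Ccr2 was present in 23 cells and Lyve1, a hyaluronan receptor of resident macrophages, in 45, and 7 cells held both. H2-Aa was present at that level in 53 cells, and 25 cells held both Lyve1 and H2-Aa, so these transcripts were not exclusive.

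**Figure D2:**
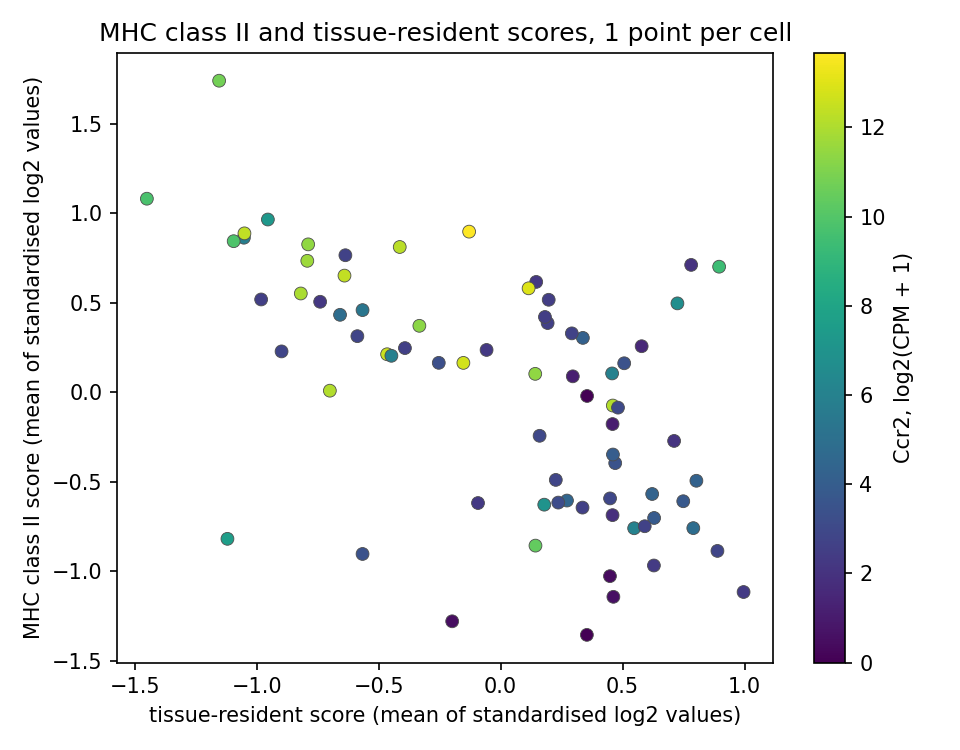
MHC class II score against tissue-resident score, both as means of standardised log2(CPM + 1) values, with 1 point for each of the 75 cells and colour for Ccr2 on the log2(CPM + 1) scale. Points run from high MHC class II and low tissue-resident scores to the reverse, with rho = -0.554.

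Of the 91 pairs of scores, 20 passed an adjusted p of 0.05, 12 with a positive and 8 with a negative correlation, and 19 of the 20 had the same sign in both sets of cells divided by genes detected. The tissue-resident score rose with the iron and haem score (rho = 0.632, p = 1e-05, adjusted p = 0.000303, r = 0.623 with p = 1e-05, r = 0.601 without 2 cells). It also rose with the lysosome score (rho = 0.472, p = 4e-05, adjusted p = 0.000607, r = 0.514 with p = 1e-05, r = 0.469 without 2 cells) and with the complement score (rho = 0.404, p = 0.00045, adjusted p = 0.00341; r = 0.593, p = 1e-05; r = 0.523 without 2 cells). In the cells with fewer and with more genes detected, rho was 0.606 and 0.656 for the iron and haem score, 0.190 and 0.711 for the lysosome score, and 0.272 and 0.489 for the complement score. These 3 scores fell with both the MHC class II and the monocyte-derived score, with rho from -0.351 to -0.461. The immediate early score rose with the inflammatory score (rho = 0.436, p = 9e-05, adjusted p = 0.00102; r = 0.434, p = 0.00011; r = 0.461 without 2 cells). Without Nfkbia, Nfkbiz and Tnfaip3 in the inflammatory list rho was 0.113. The pair with opposite signs was glycolysis and the respiratory chain, at rho = 0.329 over all cells (adjusted p = 0.0209), -0.0275 in cells with fewer and 0.414 in cells with more genes detected. Its rank correlation was 0.0859, and no longer passed, after adjustment for genes detected per cell.

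**Figure D3:**
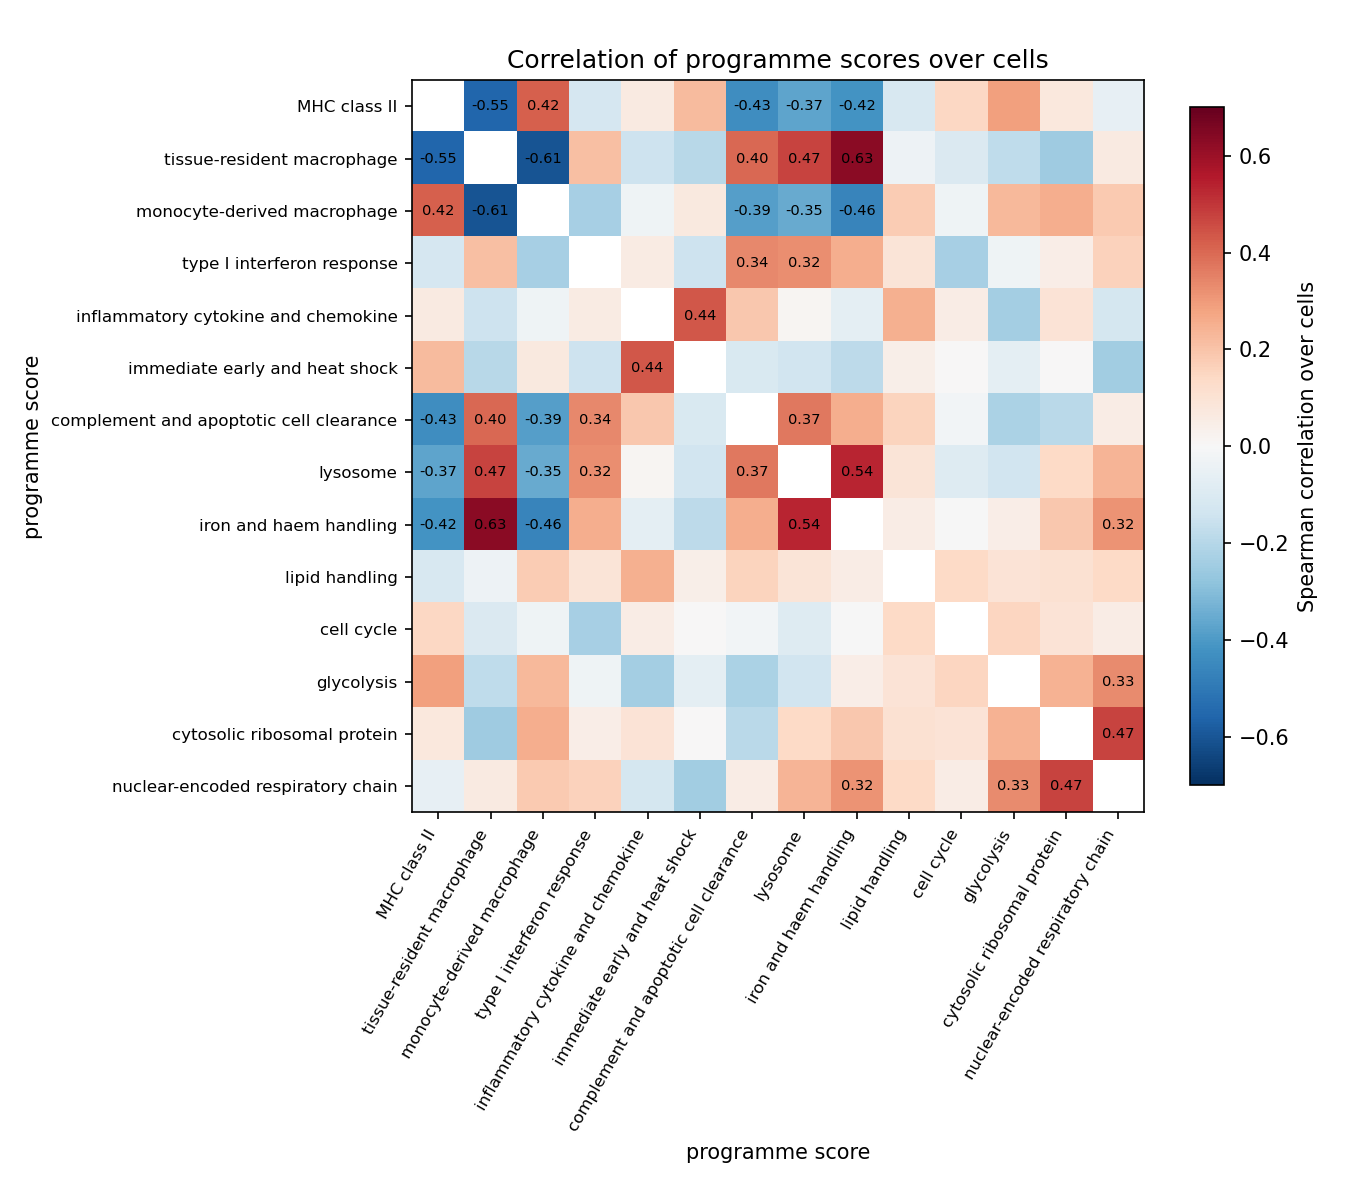
Spearman correlation over the 75 cells between the scores of the 14 programmes, on a colour scale from blue (negative) to red (positive), with values printed for the 20 pairs past an adjusted p of 0.05 and the diagonal left blank. The tissue-resident score correlates at 0.63 with the iron and haem score and at -0.61 with the monocyte-derived score.

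Among 8341 genes tested against the MHC class II score, members of that list left out, 26 rose and 32 fell with it (Spearman permutation test, adjusted p under 0.05). With values below 10 CPM set to 0, an alternative added after the data were examined, 5 rose and 15 fell. The genes that fell were led by Lyve1 (rho = -0.623, adjusted p = 0.00834), the scavenger receptor Stab1 (rho = -0.579), Rnase4 (rho = -0.562), Pf4 (rho = -0.520), Ctsb (rho = -0.500), Folr2 (rho = -0.490), Cbr2 (rho = -0.489), Cd63 (rho = -0.479), Itm2b (rho = -0.466) and Ninj1 (rho = -0.465). Of the 16 tissue-resident genes all had a rho below 0, and 7 passed over all genes tested and 12 adjusted over the list alone, among them F13a1 (rho = -0.444) and, named after their values were seen, Timd4 (rho = -0.440) and Gas6 (rho = -0.428). Of 13 complement and clearance genes 2 passed over all genes, C1qc (rho = -0.459) and C1qa (rho = -0.407), and 7 adjusted over the list alone, all falling. In cells with fewer and with more genes detected, rho was -0.369 and -0.489 for C1qc and -0.0626 and -0.668 for C1qa. Lysosome genes fell in 2 of 19 cases over all genes, Ctsb and Cd63, and in 4 adjusted over the list alone, which added Grn and Cd68. No iron or lipid gene passed over all genes. Adjusted over the list alone the iron genes Slc40a1, Ftl1 and Blvrb fell, the lipid genes Abca1, Apoe and Trem2 fell and Lgals3, Abcg1 and Lpl rose. No gene of the interferon, immediate early, cell cycle, ribosomal or respiratory chain lists passed either way. Of the 16 general macrophage markers 3 fell over all genes tested, Maf, C1qa and C1qc, and adjusted over the list alone 7 fell and Mpeg1 rose. Among markers of other cell types Pf4 alone passed over all genes. Adjusted over the list alone Tnnt2 (rho = -0.362), 1 of 4 cardiomyocyte genes that all had a rho below 0, fell and Batf3 (rho = 0.291) rose. Csf3r (rho = -0.255) and Mbp (rho = 0.287), each the only gene tested of its list, had an unadjusted p of 0.0278 and 0.0130. Members outside the first 4 of their list, here and among the genes that rose, were named after their values were seen.

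The genes that rose with the MHC class II score were led by Cd52, a surface antigen of the monocyte-derived list (rho = 0.568, adjusted p = 0.00834). It was followed by A230006K03Rik (rho = 0.564), Lilra6 (rho = 0.536), Emb (rho = 0.526), Cpeb3 (rho = 0.499), Rab11fip1 (rho = 0.488), the lectin Clec4b1 (rho = 0.466), Ramp1 (rho = 0.460), the glycolytic enzyme Pfkp (rho = 0.451) and Dock10 (rho = 0.451). Several of these were detected in few cells: Rab11fip1 was above 0 in 9 cells, and A230006K03Rik and Cpeb3, above 0 in 25 and 26 cells, never reached 10 CPM. With values below 10 CPM set to 0, only Cd52 and Clec4b1 of these 10 passed. Pearson's r for the 20 named genes had the same sign as rho in each case. It ran from 0.350 for Dock10 to 0.592 for Cd52 and from -0.648 for Lyve1 to -0.444 for Ctsb, with raw permutation p from 1e-05 to 0.00197. Adjusted over all genes, the Pearson permutation test was not passed by Cpeb3 (adjusted p = 0.0706), Pfkp (0.0702) and Dock10 (0.142). Without the 2 farthest cells every rho lay beyond 0.41 in size. In cells with fewer and with more genes detected, rho was 0.302 and 0.791 for Cd52, 0.144 and 0.668 for Clec4b1, and 0.184 and 0.664 for Dock10. For all 20 named genes except Itm2b (-0.530 and -0.469) rho was larger in size in the cells with more genes detected. Of the 7 monocyte-derived genes 1 passed over all genes and 3 adjusted over the list alone: Cd52, Ccr2 (rho = 0.405) and Lsp1 (rho = 0.346). The chemokine Ccl4 (rho = 0.436) was the 1 inflammatory gene to pass. None of 58 channel, exchanger, pump and receptor genes passed over all genes tested, with 9 at an unadjusted p under 0.05. Adjusted over the list alone, 1 of 7 potassium channel genes passed, Kcnq1 (rho = 0.326), which rose and was above 0 in 12 cells.

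The 20 most variable genes for their mean level were headed by Retnla, which encodes a secreted protein of alternatively activated macrophages. It averaged 3695 CPM, reached 1000 CPM in 13 cells and was highest at 57872 CPM. Most of the rest owed their rank to a single cell: 17 of the 20 had over 50% of their CPM in 1 cell, and 12 over 90%, among them Klhl22, C3, Cd207, Tpx2 and Mmp12. Cd74 was the only MHC class II gene among them. Ranked instead by the excess of the log variance of log2 values over its own lowess trend, H2-Aa, H2-Eb1, Cd74, Retnla, Poldip3 and H2-Ab1 came first. Of these 20 genes 2 were shared with the first ranking. The largest mean silhouette, at 6 clusters of 21, 10, 12, 13, 18 and 1 cells, was 0.131, and 7 of 100 tables in which each gene had been permuted over cells gave one as large. In 100 subsamples of 90% of the cells the median adjusted Rand index against the full clustering was 0.417, with a range from 0.178 to 0.639. At least 14 of the 16 macrophage markers were above 0 in at least 50% of the cells of every cluster, with the fewest in cluster 2. Detection above 0 cannot exclude another cell type, so the clusters are given by number only and no cell type was assigned.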

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

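Thinning to 250000 reads, setting values below 10 CPM to 0 and keeping both near-identical libraries (76 cells) were chosen after the data were examined; the other alternatives were planned. The correlation of MHC class II and tissue-resident scores kept its sign and passed under all 11 alternatives, with rho from -0.605 to -0.505 and an adjusted p of at most 0.000303. Counts of coherent programmes (11 to 13 of 14) and of correlated pairs (18 to 29) stayed within 1.5 times the reported counts. Of 220 repeats of the 20 called pairs, 10 no longer passed and none reversed. These involved lysosome with interferon, complement with interferon, glycolysis with respiratory chain, and iron with respiratory chain, and the cause was not tested. Detection depended on threshold and depth. The median listed gene was in 64.0% of cells above 0 CPM, 37.3% at 10 CPM and 47.3% after thinning. The 17 channels, exchangers and receptors in at least 50% of cells became 9 at 1 CPM, 6 at 10 CPM and 8 after thinning. Setting values below 10 CPM to 0 changed the genes rising with the MHC class II score from 26 to 5 and those falling from 32 to 15, of which 5 and 14 were shared with the reported genes. Under that setting Cd52, Clec4b1 and the 10 falling genes among the 20 named still passed, 5 no longer passed and 3 had too few values to be tested. The rising and falling genes shared with those reported numbered 13 and 19 after thinning, 15 and 21 by Pearson correlation, 15 and 29 over genes detected in at least 20 cells, and 22 and 19 without cells in the lower quartile of genes detected. Over all alternatives 11 of 211 repeats for named genes no longer passed, with Pfkp and Dock10 losing most often. Of the 20 most variable genes, 12 recurred without cells in the lower quartile of genes detected and 2 when ranked by the excess of log2 variance over its trend. The 6 clusters became 2 with 200 genes, 2 with 5 principal components and 2 after adjustment for genes detected. Keeping both near-identical libraries changed the number of clusters to 4 and no called pair. No paired analysis was possible because the cells form 1 group. Planned correlations with Gja1 and their alternatives were not run.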

Other observations

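Correlations with the tissue-resident and immediate early scores, the use of the planned adjustment for genes detected per cell as a test of explanations, the test on cardiomyocyte genes, the mixture test and both tests on Ighm were chosen after the values were seen; the other tests were written before their results. With the tissue-resident score 81 genes rose and 58 fell among 8335 tested (Spearman permutation test, adjusted p under 0.05). The endothelin receptor Ednrb (rho = 0.686), Ninj1 (rho = 0.684), the chemokine Pf4 (rho = 0.665), Ctsb (rho = 0.633) and Ly6e (rho = 0.617) rose most, each with an adjusted p of 0.00260, and Lsp1 (rho = -0.598), Clec4b1 (rho = -0.555), Cd74 (rho = -0.554) and Fxyd5 (rho = -0.547) fell most. All 4 cardiomyocyte genes tested had a rho above 0 with this score, Myh6 (rho = 0.411) passed over all genes and Ttn (rho = 0.346) adjusted over the list alone. The dendritic cell marker Siglech (rho = 0.381, adjusted p = 0.0493) passed over all genes as well. With the immediate early and heat shock score 10 genes rose and 4 fell among 8330, among them the histone demethylase Kdm6b (rho = 0.675), Nfkbia (rho = 0.621), Nfkbiz (rho = 0.575) and Tnfsf9 (rho = 0.526), each with an adjusted p of 0.0139. The 4 that fell were the ribosomal RNA features 5_8S_RRNA (rho = -0.490, adjusted p = 0.0139) and n-R5-8s1 (rho = -0.428, adjusted p = 0.0320), Tubgcp5 (rho = -0.465) and D14Abb1e (rho = -0.457). The 2 ribosomal RNA features lay near the floor. 5_8S_RRNA was above 0 in 10 cells and at 10 CPM in 0, with a mean of 0.384 CPM. n-R5-8s1 was above 0 in 13 cells and at 10 CPM in 2, with a mean of 0.655 CPM. RNA or library quality that moves with this score was not excluded.

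The 10 cells of cluster 2 had a median overlap of 0.875 in subsamples of the cells, against 0.271 to 0.667 for the other clusters of several cells. Over the 7 alternative clusterings the overlap ranged from 0.189 to 1 with a median of 0.714, and that of cluster 1 from 0.313 to 0.826 with a median of 0.656. The lowest overlap of cluster 2 came with log2 values adjusted for genes detected, and its cells had the most genes detected, with a median of 3803.5 against 2465 to 3304 in the other clusters. Ear2 averaged 860 CPM in these cells and 0.665 CPM in the rest, and Aldh1a2, which makes retinoic acid, 284 and 0.146 CPM; F10, Ptgir, Kcne3 and Kcnq1 were among the first 10 genes by fold as well. These genes helped to define the cluster, so the levels describe it and are not a test. Its median monocyte-derived score was 1.27 and its median tissue-resident score -0.806.

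The fall of the tissue-resident score with rising MHC class II score was weighed against technical sources. Adjusted for genes detected per cell the rank correlation was -0.555 (bootstrap 95% interval -0.736 to -0.336), and in the 33 cells with no cardiomyocyte gene above 0 it was -0.770 (-0.888 to -0.575). With values below 10 CPM set to 0 it was -0.505 (-0.703 to -0.279). These intervals lay below the bound of -0.2 set for each of these explanations as the whole cause. Only 4 of the 15 listed cardiomyocyte genes had values, so cells without them may still have held other cardiomyocyte RNA. With every cell rescaled without MHC class II genes the correlation was -0.539 (-0.724 to -0.316), also below -0.2. Those genes took at most 17.4% of the CPM of a cell. Rescaling could therefore move the other values only slightly, and no conclusion is drawn from it. Whether the cells form separate MHC class II low and high groups stays open, since 2 normal distributions changed the Bayesian information criterion by -0.440 against 1. Apart from this mixture test and the tests on Ighm below, no biological explanation was tested for this or the following patterns. The labels give 1 group and name no animal or chip, so differences between animals or chips stay open.

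Ighm reads in most cells were weighed against B cells caught with macrophages, which the sort gate on B220 would remove. Of 51 cells with Ighm at 10 CPM 3, or 5.88% (1.23 to 16.2%), also held Cd79b at 10 CPM, below the 50% set for B cells or doublets. That bound was set after the values were seen. Cd79b reached 10 CPM in only 5 of the 75 cells, so 50% could not have been reached and the share is descriptive. A link with the tissue-resident state of the cell stays open, since the rank correlation of Ighm with that score was 0.141 (bootstrap 95% interval -0.106 to 0.376). Free RNA from lysed cells was not tested.

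The rise of the immediate early score with the inflammatory score was not removed by adjustment for genes detected per cell, which gave 0.431 (bootstrap 95% interval 0.228 to 0.587). Without Nfkbia, Nfkbiz and Tnfaip3, early response genes within the inflammatory list, it was 0.113 (-0.115 to 0.324), within the bounds of -0.2 and 0.2 set before, although the interval passes 0.2. That the estimate and not its whole interval was held to these bounds was settled after the interval was seen. The correlation may rest largely on these 3 genes, and a weaker link with cytokine and chemokine transcripts stays open. A candidate source of the shared early response is the enzymatic digestion and sorting, which was not tested.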
